A study of Rattus norvegicus with 16 samples.

How the data were processed

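Protein interaction profile sequencing libraries were made from primary rat cortical neuron cultures, control or treated with 10 µM NMDA. Per the labels' protocols, neurons of 15 or 21 days in vitro were treated for 4 or 24 hours, and which age and duration apply to these libraries is not stated. The labels' extraction text speaks of purified nuclei from 3 grams of tissue, which does not describe cultured neurons, and gives the molecule as total RNA, so whether nuclear or whole-cell RNA was probed is not settled. Libraries were sequenced as single reads of 50 bases. Per the submitters' processing notes, the tools were cutadapt 1.2.1 and TopHat2 2.0.10 with the rn6 genome, in no stated role or order. Per the labels, the lists of PPS carry the name CSAR and a false discovery rate of 5%. The peak names in each deposited list show that it joins peaks of the ssRNase and dsRNase libraries of 1 replicate. The deposited lists hold, for each PPS, the chromosome, start, end, names of the peaks merged into it with their RNase, 1 score per peak and the strand. The deposited score has no stated scale. It served only to rank or filter PPS within a list, and the score of a PPS was the highest of its peaks. PPS ranged from 1 to 1870 bp. Structure profiles, messenger RNA sequencing and reads were not analysed here. No count of reads accompanies a PPS, so no count model was applied.

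Groups and replicate numbers came from the sample titles. Lists, not libraries, were the unit, with 2 per group. Positions are printed 1-based on rn6. The gene table at hand belongs to another assembly and no rn6 sequence or annotation was used, so PPS were assigned to no gene, exon, intron or untranslated region. The planned tests of genomic features, PPS per gene, gene lists, gene-list shares of specific sites, and sequence composition and motifs were therefore not run, and regions are named by position. Shares per chromosome and strand stood in for features.

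Numbers, covered lengths, median lengths, median scores and shares were compared by exact two-sided permutation tests of the difference of means over the 4 lists, with Benjamini-Hochberg adjustment over chromosomes. Overlap counted PPS on the same strand sharing at least 1 bp. Sites were formed by joining overlapping PPS of all lists per strand, and their presence was compared for the treatment grouping and for both other groupings of the lists into pairs. For windows, PPS were assigned by midpoint to stranded 100 kb windows, and log2(PPS per 10000 PPS + 0.5) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend) in windows with at least 8 PPS over the 4 lists, at a Benjamini-Hochberg adjusted p under 0.05. Log2 differences on this scale understate changes of sparse windows. Set operations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The rule for named items, fixed before the data were examined, took the 3 windows per direction with the largest difference past the threshold, or, as happened, those with most treatment-specific sites. It also took the 3 treatment-specific sites per direction with the highest lower score of their 2 lists.

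Blocks of peaks were compared pairwise within each chromosome when both held at least 10 PPS made of a single peak and lay in different lists or on different strands. A pair was called shared when over 10% of the smaller block's single-peak PPS had the same start, end and score in the other. Blocks of at least 20 peaks were tested for strand. A block was called off-strand when its counts over 10 kb bins correlated better, on average, with the other strand's blocks than its own strand's. A block of any size was called early-ending when its last peak lay before 90% of the last position on that chromosome. The Y chromosome and mitochondrial genome were left out of both strand and end tests. These definitions were set after seeing the data. The comparisons were repeated on the chromosome strands where all 8 blocks passed.

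The site code was tested on 2000 simulated sites of 5 presence patterns and found 100% of each pattern. The window model was tested on counts simulated for the real windows with 200 changed ones, 100 by 2-fold and 100 by 4-fold. Changed windows averaged at least 5 PPS per list, and all windows of a simulation shared 1 spread. The estimate of that spread gives most weight to the windows richest in PPS. With the within-group spread of the lists as deposited (9485 windows) it recovered 0% and 1%, and with that of the separate chromosome strands (938 windows) 13% and 78%, with 1 false call. Alternatives covered score threshold, thinning to the smallest list, PPS length, merging, overlap rule, strand, pseudocount, filter, scaling, protected bases, variance model, window size, replicate block and leaving out each list. RNase subsets, equal numbers of PPS per RNase, windows with strand ignored, the separate chromosome strands and 18 further settings for windows on those strands were added after seeing the data. The ssRNase PPS and dsRNase PPS of the subsets are all PPS with at least 1 peak from that RNase. PPS with peaks from both RNases therefore entered both subsets. The spread used in the window simulation was changed, also after seeing its result, from a median-based estimate that fell to its lower bound to a moment estimate.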

Results

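Primary cortical neurons from embryonic day 18 Sprague–Dawley rats were grown in culture and left untreated or exposed to N-methyl-D-aspartate (NMDA), an agonist of the ionotropic glutamate receptors that carry its name and that, in excess, drives excitotoxic injury. The question put by the submitters was how excitotoxicity alters the binding of proteins to RNA, together with RNA folding and transcript levels. Protein interaction profile sequencing (PIP-seq) was used, in which crosslinked RNA is digested either before or after removal of protein, so that stretches protected only while protein is present are read out as protein-protected sites (PPS). Per replicate, 4 libraries were made, by crossing 2 RNases with the presence or prior digestion of protein. RNase ONE cuts single-stranded RNA (ssRNase) and RNase V1 cuts paired RNA (dsRNase). The 16 libraries came from 2 control replicates and 2 NMDA replicates, numbered 2 and 3 in each group. The values analysed were the 4 deposited lists of PPS, each combining the 4 libraries of 1 replicate, with genome positions in the rn6 build and a score per peak that is the submitters' own. Read numbers per library are not given with the lists, so sequencing depth is unknown. The list is the replicate in every comparison, n is 2 per group, and the smallest two-sided exact permutation p that this allows is 0.333. No label says whether the replicates were separate cultures, so the spread between lists may be technical.

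Parts of the lists were not independent of each other. A block was defined as the peaks of 1 list, 1 RNase, 1 chromosome and 1 strand, which gave 367 blocks. Of 2405 pairs of blocks compared on the same chromosome, 52 held the same peaks, with identical start, end and score, at 51.7% or more of the smaller block. In the remaining pairs the highest such share was 0.694%. The same scores in the same order, with the same steps in peak numbering, filled both blocks in 44 of the 52 pairs. Minus-strand peaks of the NMDA replicate 3 ssRNase libraries were those of the control replicate 3 dsRNase libraries on 22 chromosomes, the mitochondrial genome included. Plus-strand dsRNase blocks of NMDA replicate 3 shared peaks with plus-strand ssRNase blocks of control replicate 2 on 9 chromosomes, in full on 7, among them chromosomes 3, 7 and 8, and in part on chromosomes 5 and 15. On 8 chromosomes, plus-strand ssRNase blocks of NMDA replicate 3 shared peaks with minus-strand ssRNase blocks of control replicate 2, in full on 6, including 1, 2 and X, and in part on chromosomes 6 and 14. In all, 50 of the 52 pairs joined a control list with an NMDA list, and 16 joined opposite strands.

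In 41 blocks the positions of peaks followed those of the blocks labelled with the opposite strand, and 25 of these blocks were outside the shared set. Their median correlation over 10 kb bins was -0.0716 with blocks of their own strand and 0.425 with blocks of the other strand, whereas 203 tested blocks without any of these features had medians of 0.550 and -0.120. Ending before 90% of the length reached on that chromosome was found in 19 blocks, 6 of them with neither of the other features. Counting all 3 features, 135 blocks were affected, holding 37.2% of all peaks. The share was 43.8% in control replicate 2, 34.2% in control replicate 3, 9.92% in NMDA replicate 2 and 61.3% in NMDA replicate 3. The plus strands of chromosomes 11, 12, 16, 17, 18, 19 and 20 had none of these features in any of their 8 blocks. They are called the 7 separate chromosome strands here, and most comparisons are given for the lists as deposited and again for them, a restriction chosen after seeing the data. A block moved whole to another list on its own strand, with no copy elsewhere, would not be found this way. Such moves stay possible on the 7 strands. Plus-strand dsRNase blocks of control replicate 3 were off-strand on every other chromosome tested for strand. NMDA replicate 2 held 1547 ssRNase and 2117 dsRNase plus-strand peaks on chromosome 8, against 230 and 1000 on chromosome 11. Its chromosome 15, outside the 7, had a balance like that of chromosome 11, with 195 and 1029.

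**Figure D1:**
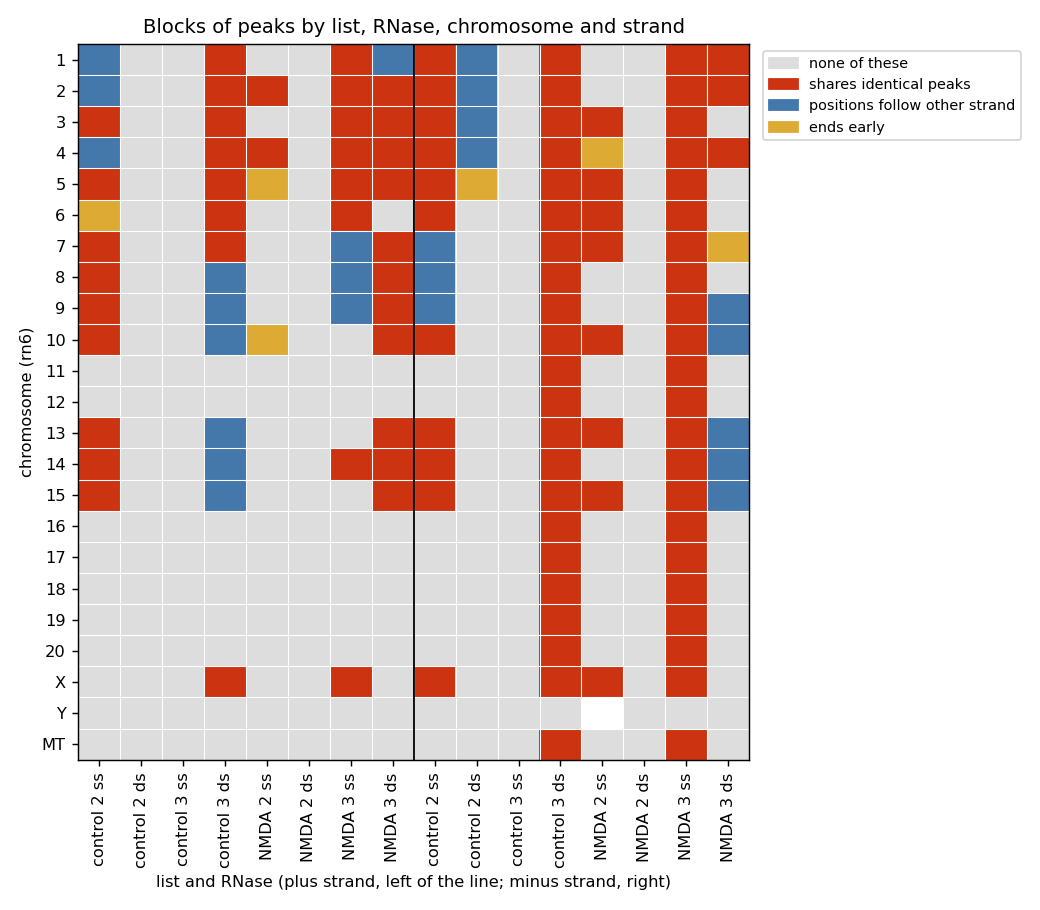
Each cell is 1 block of peaks, by chromosome (vertical axis) and by list and RNase (horizontal axis, plus strand on the left and minus strand on the right), coloured by the first feature that applied. The plus strands of chromosomes 11, 12, 16, 17, 18, 19 and 20 are free of coloured cells across all 8 columns, as are those of the Y chromosome and the mitochondrial genome, which were not tested for strand and end.

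The lists held similar numbers of PPS in both groups. Control replicate 2 held 97311 PPS and control replicate 3 held 66261, against 85378 in NMDA replicate 2 and 80792 in NMDA replicate 3. Group means were 81786 ± 21956 for control and 83085 ± 3243 for NMDA (SD, n = 2), and the exact permutation test gave p = 1. Chromosomes 11, 12 and 16 to 20, plus strand, gave much less spread, with 8840 ± 89.1 PPS in control and 9356 ± 236 in NMDA (SD, n = 2). There both NMDA lists lay above both control lists, a ratio of 1.06 with an exact p = 0.333, the smallest this design can give. Median PPS length was 51 and 54 bp in the control lists and 50 bp in both NMDA lists. Covered sequence came to 5618839 and 4010163 bp in control and 4646311 and 4778477 bp in NMDA (exact p = 1), and on the separate strands to 549188 and 454329 bp in control and 501258 and 610361 bp in NMDA (exact p = 0.667). Median lengths on the separate strands were 54 and 46 bp in control and 50 and 52 bp in NMDA. Median scores were 6.82 in all lists but NMDA replicate 2, where the median was 7.43, both as deposited and on the separate strands.

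In both NMDA lists as deposited, a smaller share of PPS came from ssRNase alone and a larger share from dsRNase alone. Many shared blocks, however, carried a different RNase label in each list. Peaks labelled ssRNase in NMDA replicate 3 were labelled dsRNase in control replicate 3 on 22 chromosomes. Peaks labelled dsRNase in NMDA replicate 3 were labelled ssRNase in control replicate 2 on 9. The RNase of such peaks is uncertain. PPS from ssRNase alone made up 43.8% and 55.0% of the control lists and 27.8% and 41.3% of the NMDA lists (means 49.4% ± 7.87 and 34.6% ± 9.57, SD, n = 2, exact p = 0.333). PPS from dsRNase alone made up 47.8% of control replicate 2 and 37.2% of control replicate 3, against 59.3% of NMDA replicate 2 and 48.1% of NMDA replicate 3. The means were 42.5% ± 7.49 in control and 53.7% ± 7.92 in NMDA (SD, n = 2, exact p = 0.333). NMDA replicate 3 thus lay barely above control replicate 2. The RNase balance of NMDA replicate 2 differed between chromosomes, as given above. On the separate strands neither share separated the groups. There 11.4% of PPS in NMDA replicate 2 came from ssRNase alone, with the other lists between 37.0% and 39.1% (exact p = 0.667), and dsRNase alone gave 51.8% ± 3.24 in control and 62.6% ± 23.1 in NMDA (SD, n = 2, exact p = 1). PPS supported by both RNases made up 8.08% ± 0.38 of the control lists and 11.7% ± 1.65 of the NMDA lists (SD, n = 2, exact p = 0.333). That share did not separate the groups on the separate strands either, where control replicate 2 had 13.5%, control replicate 3 had 6.78%, NMDA replicate 2 had 9.69% and NMDA replicate 3 had 16.6%.

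**Figure D2:**
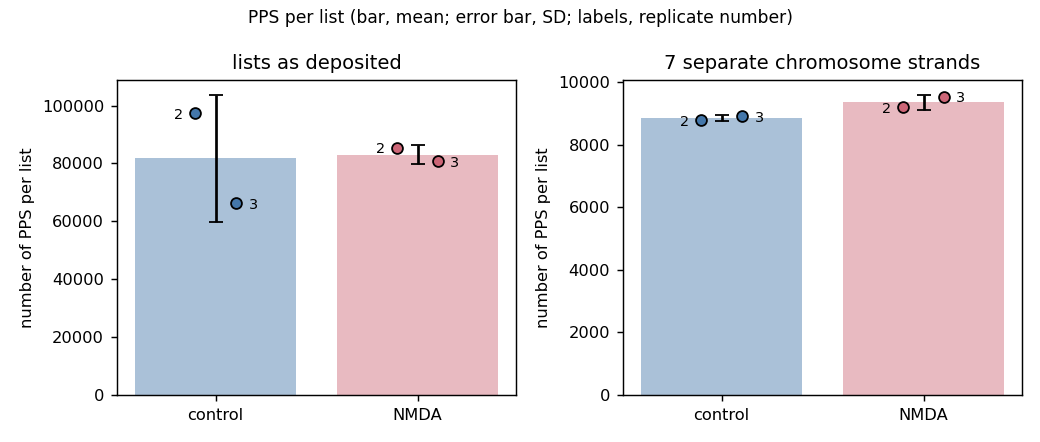
Number of PPS per list (vertical axis, from 0) in control and NMDA, for the lists as deposited (left) and on the 7 separate chromosome strands (right). Bars are group means, error bars SD (n = 2) and points single lists labelled by replicate number. The control lists lie at 97311 and 66261 on the left and at 8777 and 8903 on the right.

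The plus strand held 53.3% and 51.8% of PPS in the control lists and 58.0% and 53.3% in the NMDA lists as deposited (exact p = 0.667). The difference of means, 3.09 percentage points, was 0.740 without NMDA replicate 2 and 5.43 without NMDA replicate 3. Off-strand blocks held 29.9% of peaks in control replicate 2, 13.0% in control replicate 3, 0% in NMDA replicate 2 and 14.8% in NMDA replicate 3. The strand of these peaks is uncertain, so the difference cannot be read as an effect of treatment. The separate strands are all plus strands and cannot check it. Chromosome 1 held the most PPS in every list as deposited, from 8.74% in NMDA replicate 3 to 14.9% in NMDA replicate 2, so the NMDA replicates differed by more than the treatment means of 13.4% and 11.8% did. Shares did not overlap between the groups on 4 of 23 chromosomes, chromosomes 10, 14, 15 and X, where chance gives 33.3% of chromosomes. Chromosome 14 carried 3.48% ± 0.082 of control PPS and 3.87% ± 0.196 of NMDA PPS (SD, n = 2, exact p = 0.333, adjusted p = 1). There a minus-strand ssRNase block of control replicate 2 ended at 38.8% of the length reached. Blocks on chromosomes 10 and 15 also ended early, and none did on X. Among the 7 separate chromosome strands, chromosome 12 took 15.7% ± 0.61 of the control PPS and 13.5% ± 0.848 of the NMDA PPS. Chromosome 17 took 16.7% ± 0.353 and 18.0% ± 0.27, and chromosome 16 took 15.7% ± 0.498 and 16.7% ± 0.464 (SD, n = 2, exact p = 0.333 for each). With chromosome 20, 4 of these 7 chromosomes had shares that did not overlap between the groups.

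Overlap between lists did not follow treatment. Averaged over both directions, the share of PPS overlapping by at least 1 bp on the same strand was 23.0% between the control lists and 35.9% between the NMDA lists. Pairs of different treatment overlapped by 31.1% to 37.9%, and the mean was 29.5% for the same treatment and 33.5% for different treatments. PPS with identical coordinates on either strand numbered 15915 between control replicate 2 and NMDA replicate 3 and 11966 between control replicate 3 and NMDA replicate 3, but 184 between the control lists. The separate strands had 16 to 88 identical PPS per pair. Their overlaps were 38.4% between the control lists, 42.9% between the NMDA lists, and 35.0% to 48.1% between lists of different treatment, a mean difference of -1.75 percentage points. The 6 pairs share lists and are not independent, so no p was computed.

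Sites present in both NMDA lists and in neither control list would be the strictest candidates for protection gained with NMDA. Merging all PPS per strand gave 210919 sites, of which 144656 were in a single list and 8161 in all 4. Both NMDA lists and no control list held 5226 sites, and both control lists and no NMDA list held 3204, together 8430. Grouping the lists by replicate number in place of treatment gave 18790 sites, and the remaining grouping gave 11629. Treatment-specific sites thus came to 0.554 of the mean of the other groupings. For the 7 separate strands the numbers were 620 NMDA-specific and 585 control-specific sites, together 1205, against 1622 and 1369 for the other groupings, a ratio of 0.806.

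**Figure D3:**
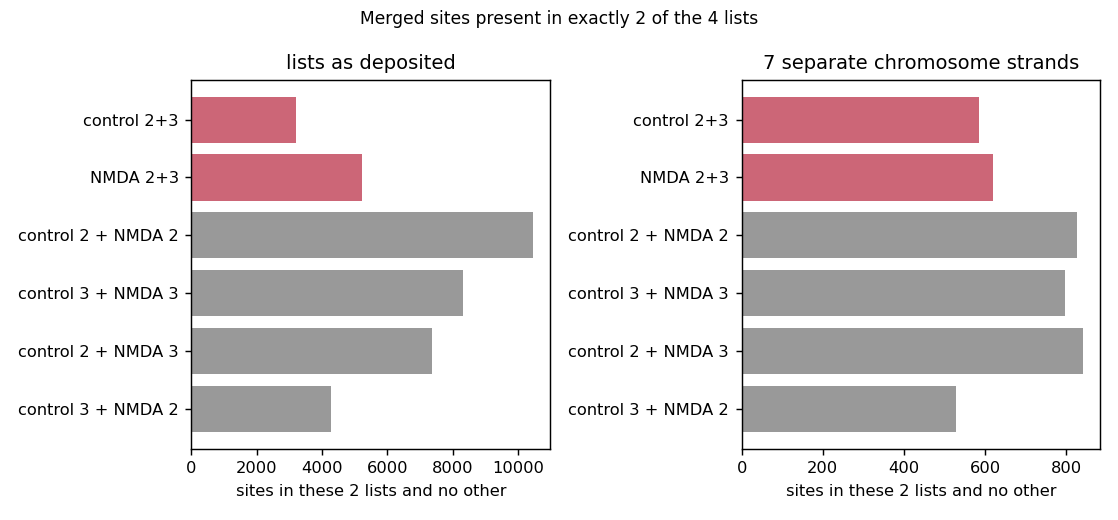
Number of merged sites (horizontal axis) found in exactly the 2 lists named on the vertical axis, for the lists as deposited (left) and the 7 separate chromosome strands (right). Red bars are pairs of the same treatment and grey bars pairs of different treatment. On the left the bar for both control lists is the shortest, at 3204 sites.

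Among the NMDA-specific sites, the highest scores in both lists belonged to chromosome 5 at 63807453 to 63807625, chromosome 1 at 161882532 to 161882632 and chromosome 1 at 214385045 to 214385190, all on the plus strand, with lower scores of 23.48, 21.46 and 20.07. The leading control-specific sites were all on the plus strand of chromosome 2, at 29687558 to 29688375, 29678565 to 29678797 and 231248376 to 231248554, with lower scores of 18.42, 16.33 and 16.01. All of these lie on chromosome strands with 4 or 5 affected blocks, and when strand was ignored 0 of the 6 remained specific to a treatment. Leading NMDA-specific sites on the separate strands lay on chromosome 18 at 56047249 to 56047354, chromosome 17 at 63487999 to 63488142 and chromosome 19 at 26167831 to 26167902. Their lower scores were 17.65, 16.01 and 16.01. The control-specific ones lay on chromosome 12 at 25235524 to 25235589 and at 49505349 to 49505416, and on chromosome 16 at 6055395 to 6055447, each with a lower score of 11.7. Of these 6 sites, 6 stayed specific with strand ignored and 4 when lists were thinned at random to the smallest. Among PPS holding an ssRNase peak 2 stayed specific, and among those holding a dsRNase peak 3 did.

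The number of PPS per stranded 100 kb window, a measure that needs no gene models, was compared between treatments over 9485 windows. With limma, 0 windows were higher and 0 were lower in NMDA at an adjusted p under 0.05, and 280 (2.95%) had an unadjusted p under 0.05. Both other groupings of the lists gave more windows at that unadjusted p, 435 by replicate number and 361 for the remaining one. Simulated changes of 4-fold in windows of this spread were recovered in 1% of cases, so changes of that size would rarely be called in the lists as deposited. Leaving out control replicate 3 gave 280 windows lower in NMDA and 0 higher, 0 of the 280 on the separate strands. The 7 separate chromosome strands held 938 windows, with 0 higher and 0 lower at an adjusted p under 0.05 by limma and a smallest adjusted p of 0.336. There, 94 windows (10.0%) had an unadjusted p under 0.05, 46 of them higher and 48 lower in NMDA. Grouping the same lists by replicate number gave 29 such windows and the remaining grouping gave 19. With PPS holding a dsRNase peak, however, the treatment grouping gave 44 against 56 for replicate number. With PPS holding an ssRNase peak it gave 23 against 30 for the remaining grouping. PPS with peaks from both RNases entered both subsets. Without control replicate 2 limma called 11 windows of these strands higher and 7 lower, without control replicate 3 it called 25 and 6, and without either NMDA list it called 0, with 54 and 49 windows at an unadjusted p under 0.05. In simulations at 1 spread common to these windows, 78% of 4-fold and 13% of 2-fold changes were recovered. The estimate of that spread leans on the windows richest in PPS, so recovery at the spread of typical windows is not known. There 200 of the 938 windows were changed, all of them richer in PPS than the filter requires. Recovery in sparser windows, or with fewer changed ones, was not tested.

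Windows with most control-specific sites lay on the plus strand of chromosome 2. From 29600001 to 29700000 there were 36 such sites, with 83 and 68 PPS in the control lists and 0 in both NMDA lists (limma adjusted p = 0.144). From 231200001 to 231300000 there were 27, with 112 and 58 PPS in control and 0 in both NMDA lists (limma adjusted p = 0.144). The limma adjusted p of both was 0.0240 when windows with at least 1 PPS entered, 0.0304 for PPS above each list's median score and 0.00628 with the replicate number as a block, and from 0.0592 to 0.998 in the other settings, among them 0.644 when lists were thinned at random and 0.903, 0.816 and 0.976 without control replicate 2, NMDA replicate 2 and NMDA replicate 3. On the minus strand of the same windows the NMDA lists held 79 and 52 PPS in the first and 115 and 78 in the second. Control replicate 3 held 58 and 79 there, and control replicate 2 held 0 in each. On this chromosome the plus-strand ssRNase block of control replicate 2 and dsRNase block of control replicate 3 were off-strand. The plus-strand counts of these windows therefore do not show a loss with NMDA. On chromosome 1, from 215900001 to 216000000, 17 control-specific sites stood beside 149 and 19 PPS in control and 0 and 30 in NMDA. The window with most NMDA-specific sites was on chromosome 14, plus strand, from 46600001 to 46700000, with 27 such sites and 44 and 17 PPS in control against 100 and 94 in NMDA (log2 difference 1.63, SE 0.347, limma adjusted p = 0.938). On chromosome 2, plus strand, the windows from 94500001 to 94600000 and from 187500001 to 187600000 held 16 NMDA-specific sites each. All of these windows lie on chromosome strands with affected blocks.

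On the 7 separate strands, the window of chromosome 17 from 75300001 to 75400000 had 12 sites specific to NMDA, 7 specific to control and 12 in all 4 lists, with 104 and 79 PPS in control and 126 and 152 in NMDA. Nearby, from 75500001 to 75600000, 12 NMDA-specific and 6 control-specific sites were found with 54 and 40 PPS in control against 85 in each NMDA list (log2 difference 0.78, SE 0.225, limma adjusted p = 0.485). Among all strands the log2 difference of this window was 0.77, and with PPS holding an ssRNase peak it was -0.0118. Chromosome 16 from 77200001 to 77300000 had 8 NMDA-specific sites and 1 control-specific site. Its PPS numbered 22 and 21 in control and 48 and 54 in NMDA (log2 difference 1.15, SE 0.202, limma adjusted p = 0.336). Among all strands the log2 difference was 1.06, and it was 0.29 with PPS holding an ssRNase peak and 0.56 with PPS above each list's median score. Chromosome 18 from 25900001 to 26000000 had 7 control-specific sites and 2 NMDA-specific ones. It held 26 and 14 PPS in control and 12 and 10 in NMDA (log2 difference -0.86, SE 0.378, limma adjusted p = 0.558), and among all strands the log2 difference was -0.66, or -0.40 with a pseudocount of 2.

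**Figure D4:**
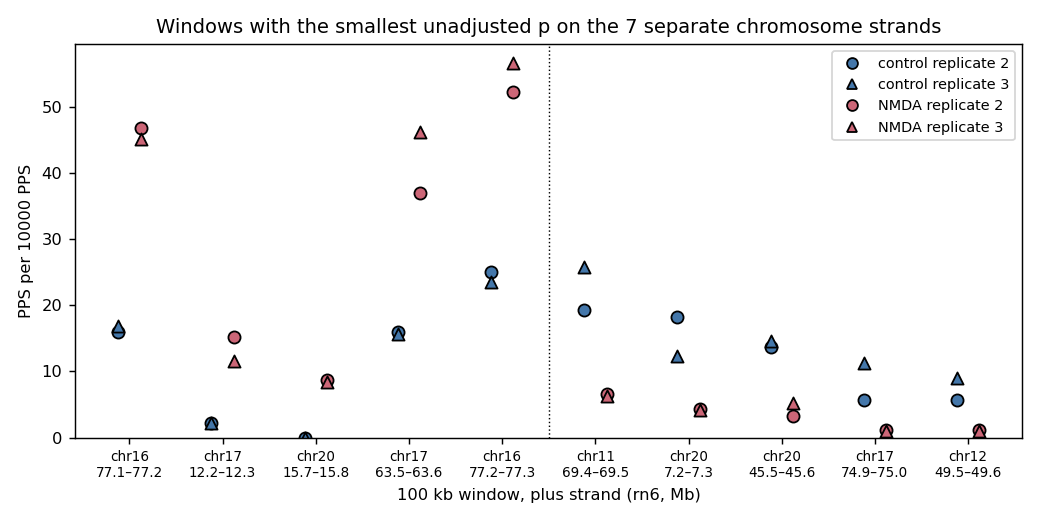
PPS per 10000 PPS of the 7 separate chromosome strands (vertical axis) in the 5 windows with the smallest unadjusted limma p in each direction (horizontal axis, left of the dotted line higher in NMDA), chosen after seeing the data. Each point is 1 list. The smallest adjusted p is 0.336, and on chromosome 16 from 77100001 the NMDA lists lie at 46.8 and 45.2, against a control mean of 16.4.

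Mitochondrial RNA, transcribed from both strands of a small circular genome, carried PPS at a far higher density than the genome as a whole, at 6.48 to 7.84 per kb of the range covered, against 23.9 to 35.0 per Mb over all chromosomes. The figure over all chromosomes divides by their length, transcribed or not, so this contrast does not measure protein protection. There were 113 and 127 mitochondrial PPS in the control lists and 114 and 105 in the NMDA lists. Merged, they formed 92 sites, and 35 of them (38.0%) were in all 4 lists, against 3.87% of all sites. At such density PPS of different lists may overlap by position alone, which was not tested, so these shares do not show that single mitochondrial sites recurred more often. Only 2 were specific to NMDA and 4 to control. On the plus strand, where no block shared peaks, 10 of 24 sites (41.7%) were in all 4 lists. Among the plus-strand sites in all 4 lists were those from 5303 to 6940, from 9820 to 11669 and from 13674 to 15280. Whether the RNA came from nuclei or whole cells is not settled by the labels, which leaves open what part of mitochondrial RNA was sampled. The minus strand includes a block shared between control replicate 3 and NMDA replicate 3.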

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

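The tests on the separate chromosome strands, on RNase subsets and on windows with strand ignored were chosen only after the results were seen. Median PPS length, -2.5 bp for NMDA minus control, became 0 for PPS above each list's median score, 1 on the separate strands and 0.5 for ssRNase PPS. Without 1 list it ranged from -4 to -1. The difference in median score, 0.305, became -0.225 for dsRNase PPS and 0 without NMDA replicate 2. The plus-strand share, 3.09 percentage points higher in NMDA, was 6.83 higher for PPS above the median score and 8.11 higher as a share of base pairs. Without NMDA replicate 2 it was 0.740 higher. Off-strand blocks leave the strand of many peaks uncertain in all of these settings. The share from both RNases, 3.60 points higher, was 8.57 higher above the median score. Overlap within minus between treatments, -4.08 points, was 1.21 for ssRNase PPS. NMDA-specific sites numbered 5226 as deposited, 2243 above the median score and 620 on the separate strands. Control-specific sites went from 3204 to 1337 and 585 in those settings, to 2021 for ssRNase and to 1192 for dsRNase PPS. The ratio of treatment-specific sites to the other groupings, 0.554, was 1.04 for ssRNase PPS. Without 1 list, NMDA-specific sites ranged from 11798 to 41574 and control-specific sites from 6041 to 54677, since the condition on that list then falls away, and 11 to 17 chromosomes had shares that did not overlap.

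Over all strands, limma called no window higher in NMDA in any setting run. Windows lower in NMDA numbered 0, except 2 when windows with at least 1 PPS entered, 2 for PPS above the median score, 2 with the replicate number as a block, and 0 to 280 without 1 list, the 280 arising without control replicate 3. The lone list is there assumed to vary like the others. The windows called in the first 3 of these settings are on the plus strand of chromosome 2, starting at 29600001 and 231200001. Both NMDA lists held 0 plus-strand PPS there, so the size of the difference depends on the pseudocount. Plus-strand blocks of both control lists on this chromosome were off-strand, and the NMDA lists held PPS on the minus strand of both windows. These calls therefore do not show a loss of PPS with NMDA. Windows at an unadjusted p under 0.05 made up 2.95%, and 1.76% with at least 1 PPS, 10.0% on the separate strands, 1.19% for dsRNase PPS, 1.66% with strand ignored and 2.56% to 15.7% without 1 list, 15.7% without control replicate 3, and 4.88% without NMDA replicate 2. The window of chromosome 17 starting at 75500001 turned from 0.77 with all PPS to -0.0118 with ssRNase PPS. On the separate strands alone, the 94 windows at an unadjusted p under 0.05 ranged from 23 with ssRNase PPS to 164 with at least 1 PPS, and the treatment grouping gave more windows than both other groupings in 12 of 14 settings, the exceptions being ssRNase PPS and dsRNase PPS. Limma called 18 and 31 windows without a control list, 0 without an NMDA list, and 1 for PPS above the median score, on chromosome 18 from 28100001 to 28200000, higher in NMDA (adjusted p = 0.00467). That window held 5 and 0 PPS in control and 8 and 13 in NMDA, with a residual variance of 5.69, against a moderated variance of 0.639 in limma. The cause of these changes was not tested.

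The replicates share only a number. With the replicate number as a block, limma called 2 windows lower and 0 higher. Deviations of same-numbered lists from their group means correlated at 0.00535 over 9485 windows and at 0.119 over 938 windows of the separate strands. Alternatives for features, genes, gene lists and motifs were not run. With depth unknown, the absence of a call sets no limit on small changes.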

Other observations

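The tests of chance, whole libraries and incomplete copies for the shared peaks, and of copied blocks for the low number of treatment-specific sites, were chosen only after the results were seen, as were the separate chromosome strands, the window pattern on them and the windows and sites named here. RNase agreement and equal RNase numbers were stated before their values were known, but after the window counts of each RNase subset had been seen.

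Some stretches of the genome held PPS in every list. The 5 windows with most PPS on the separate chromosome strands included 4 neighbours on chromosome 17, from 75300001 to 75700000, with 461, 371, 264 and 292 PPS over the 4 lists, and 1 on chromosome 11 from 34600001 to 34700000, with 261. The median window held 24. Of the sites in all 4 lists there, the one with the highest lowest score was on chromosome 17 from 31443378 to 31444685, a joined stretch of 1308 bp. Next came chromosome 11 from 58672358 to 58672922, chromosome 12 from 23816173 to 23817304 and chromosome 19 from 56228377 to 56229623. A joined site need not be protected over its whole length in each list. The longest PPS on these strands was 1308 bp in NMDA replicate 3. It was 624 bp in control replicate 2, 407 bp in control replicate 3 and 354 bp in NMDA replicate 2. Which transcripts these are was not analysed here.

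Identical peaks occurred in 52 pairs of blocks, mostly across treatments. Chance agreement of separate libraries is argued against by the other pairs, which shared at most 0.694% of peaks. For the pair of libraries identical on 22 minus strands, the plus strands shared 0% of peaks. The deposited blocks of this pair were thus not copies on both strands. Many plus-strand blocks of that control library were off-strand, however, and may not be its own. The separate chromosome strands, where they were not, were chosen in part for sharing no peaks, and blocks moved whole may lie there. A whole library entered under 2 names therefore stays open for this pair. Other kinds of shared pair were not tested in this way. A candidate explanation is that chromosome strands were mixed up when the lists were put together: in each of the 8 incomplete copies, 100% of the shorter block formed an unbroken run of the longer one from its first peak. Examples of such runs had prompted that test, which of the copies is the original stays open, and no biological explanation was tested.

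On the separate chromosome strands, 94 windows had an unadjusted limma p under 0.05 for the treatment grouping, against 29 and 19 for the other groupings. Over all strands the treatment grouping gave the fewest, 280 against 435 and 361. On the separate strands it was highest on 6 of the 7 chromosomes and in 12 of 14 settings. It was not highest with PPS holding an ssRNase peak (23 against 30) or a dsRNase peak (44 against 56). Chance spread and treatment cannot be told apart, since 3 groupings are too few for a share under 0.05. Log2 differences from PPS of ssRNase alone and from PPS of dsRNase alone correlated at r = 0.0241 (95% bootstrap interval -0.0424 to 0.0888), against -0.0645 and -0.103 for the other groupings. An r near 0 is what was stated in advance for chance, but r without any change need not be 0 given those values. A simulation added once r was known gave 0.0182 to 0.155 for a shared effect of the size of the extra variance. It drew counts with no spread between lists beyond counting error, so its range cannot be set against the observed r. Unequal RNase shares also remain possible, since with equal numbers of PPS per RNase the treatment grouping gave most windows in 13 of 20 draws (medians 48, 44.5 and 23.5). A difference in transcript abundance or protein occupancy with NMDA stays an untested hypothesis.

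Treatment-specific sites were fewer than those of the other groupings, at a ratio of 0.554 as deposited, and 3 groupings are too few for a share under 0.05 (8430 sites, lowest other grouping 11629). Copied blocks as the whole cause cannot be told apart from spread between lists: on the separate strands the ratio was 0.806 (1205 sites, lowest other grouping 1369), and its 95% bootstrap interval over windows, 0.747 to 0.863, covers counting error within these lists only. Unequal RNase shares stay open too, since equal numbers of PPS per RNase on the separate strands gave a median ratio of 0.827, with 20 of 20 draws below 1. That outcome was stated in advance as evidence against them, but the draws vary the thinning and not the lists, and on all strands, where equal numbers were not run, the ratio was 1.04 for ssRNase and 0.496 for dsRNase PPS. Those RNase subsets also part copies that carry different RNase labels, so they do not isolate the RNase shares. Differences in depth or culture between lists, and any effect of NMDA on these sites, stay open as untested.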
